A study of Mus musculus with 30 samples.

How the data were processed

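CTCF and RAD21 were profiled by ChIPmentation in trunks of B6CBAF1 mouse embryos at E10.5, from WT littermates and 6 homozygous alleles, in 14 CTCF and 16 RAD21 libraries. Per the labels, embryos came from crosses between heterozygous parents, were dissociated one by one, fixed with formaldehyde and sonicated, and the chromatin was tagmented on the beads. The authors deposited 1 peak list per library on the mm10 build, called for that library alone. Per the submitters' processing notes the tools were cutadapt 1.16, Bowtie2 2.3.5, SAMtools 1.9, Picard 2.19.0, MACS2 2.1.1.20160309 and bedtools 2.27.1, whose options were not stated. In the deposited lists each peak has a score, a display value that follows the -log10 q. The authors' signal value is a ratio, the fold enrichment of the summit over the local background of the same library. The deposited -log10 p and -log10 q are the caller's own for each peak, and each summit is given as an offset from the peak start. The lists hold no read counts, so depth was unknown, and list lengths (40011 to 88323 for CTCF, 16676 to 48102 for RAD21) describe how much was called.

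Because peaks were called separately, fold values were used as ranks within a list or as descriptions, except in 1 alternative of the rank tests, which took their log2 centred on each library's median. WT summits within 150 bp were linked, and a reference site was a group with a peak over its median summit in all WT libraries of the antibody (47658 CTCF and 20061 RAD21 sites). A library detected a site when 1 of its peaks covered that summit. The HoxD window ran from 20 kb beyond Evx2 to 20 kb beyond Hoxd1. Genes were taken from the mm10 RefSeq gene spans; exons, introns, sequence motifs and motif orientation were not analysed here. Positions are counted from 1.

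Each site's detection was compared with 5 patterns, 1 per mutated site, in which a library lacks the site exactly when its genotype includes it; a name such as Del(CBS1-3) was read as sites 1, 2 and 3. Fisher's exact test (2-sided) was adjusted by Benjamini-Hochberg over sites and patterns. Mutated sites were then assigned to positions by the 1-to-1 assignment with the fewest libraries off pattern (unique among 95040). Lost sites were those in all WT libraries and no mutant library, and gained sites the reverse. Percentiles in the HoxD window were taken over the sites found in every library of the antibody (30976 CTCF, 12932 RAD21), with 0 for no peak. WT was compared with mutant libraries that kept a site by exact permutation over 20 tests. That set of tests was chosen after the data were seen, and was corrected once because a first version had left libraries with the site mutated among the intact ones; the adjusted p of the RAD21 test at CBS4 is the corrected one.

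Rank changes were fitted with limma 3.58.1 in R 4.3.3 (robust empirical Bayes with trend), with 1 coefficient per genotype or 1 slope on the number of mutated sites, at an adjusted p of 0.05. Genotypes with 1 library were assumed to vary like the others. Gene lists were tested with camera (correlation 0.01; alternatives fry and camera with an estimated correlation), a site belonging to a list within 5 kb of a gene body. The 12 lists were the HoxD cluster, other Hox clusters, imprinted domains, protocadherin clusters, neural tube, somite and muscle, limb and lateral plate, endoderm and liver, heart, blood, and the centromeric and telomeric sides of HoxD. Haglros and Nesp were not matched in the annotation. The share of RAD21 intervals overlapping by 1 bp or more a window of 150 bp to each side of a reference (WT) CTCF site was compared by exact permutation. Other computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

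The sites named were every reference CTCF site of the HoxD window, any RAD21 peak gained there, up to 10 called sites per contrast with the largest change, the 5 strongest lost sites per antibody in Del(CBS1-5), and up to 4 genes per list. Groups, comparisons, lists and this rule were fixed before the data were examined. The alternatives were a summit within 100 bp, any peak base within 250 bp, peaks of -log10 q of at least 10, sites in at least 2 WT libraries, 1 library allowed off pattern, ranks of -log10 p, the centred log2 fold values, limma without trend and robust fitting, each genotype's own CTCF peaks, the same number of top peaks in every list, the weakest 25% of sites left out, replicate number as a block, 50 kb around genes and leaving out each library of a replicated group. For the RAD21 share each library was left out in turn, and for CBS4 each of the 12 compared; the CBS4 omissions and those of mutant libraries from the share were chosen after seeing the data. Tested on simulated data, limma recovered 4%, 40% and 64% of 50 planted CTCF shifts of 1, 1.5 and 2 normal-score units and 8%, 40% and 76% of the RAD21 shifts, with 3 and 2 false calls. All 197 planted losses among 5000 simulated sites were recovered. Every other simulated site had a peak in every library, so this did not test weak sites that real lists miss. Entries outside the main chromosomes were left out.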

Results

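CTCF, the zinc-finger protein that marks many chromatin loop anchors, and RAD21, a subunit of the cohesin ring, were mapped by ChIPmentation in trunks of mouse embryos at E10.5. ChIPmentation is chromatin immunoprecipitation in which the sequencing adapters are inserted by Tn5 transposase on the beads. The 30 libraries came from wild-type (WT) embryos and from 6 homozygous alleles of the Hoxd cluster in which CTCF binding sites (CBS) were mutated in cis. CTCF was profiled in 3 WT, 3 Del(CBS1), 1 Del(CBS1-2), 2 Del(CBS1-3), 2 Del(CBS1-4), 2 Del(CBS1-5) and 1 Del(CBS2) libraries. RAD21 was profiled in 4 WT, 3 Del(CBS1) and 1 Del(CBS2) libraries and in 2 libraries of each of the other 4 alleles. Embryos were dissociated individually, so libraries were treated as separate embryos, and Del(CBS2) (both antibodies) and Del(CBS1-2) (CTCF) had no replicates. The CTCF lists held 40011 to 88323 peaks and the RAD21 lists 16676 to 48102 peaks. The read depth behind each list was unknown, so no interval or detection floor was computed, and a site without a peak was taken as not detected rather than as unbound.

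The first comparison asked which CTCF sites of the HoxD cluster disappeared with each allele. The window around the cluster (mm10, chromosome 2, 74632989 to 74785142) held 12 CTCF sites found in all 3 WT libraries, and 3 of them disappeared from exactly the libraries of a cumulative mutation step. The site at 74694237, within the Hoxd10 span, was found in 8 of 8 libraries with that step intact and in 0 of 6 with it mutated. The site at 74691779, also within Hoxd10, was found in 10 of 10 and 0 of 4 libraries, and the site at 74686497, within the Hoxd11 and Hoxd10 spans, in 12 of 12 and 0 of 2. Hoxd10 and Hoxd11 are posterior Hox genes that pattern the trunk and limbs. The site at 74702390 and 613 bp from Gm38462, was found in 6 of 6 libraries with CBS2 intact and in 3 of 8 with it mutated. Those 3 peaks were weak, at percentiles 0.3 to 5.1 of the CTCF sites common to all lists, against 55.1 to 96.5 in WT. The site at 74715933, within the Hoxd3os1 and Hoxd3 spans, was found in 4 of 4 libraries with CBS1 intact and in 2 of 10 with it mutated. The labels give no coordinates, so each mutated site was assigned by its pattern of loss, which placed CBS5, CBS4, CBS3, CBS2 and CBS1 in this order from 74686497 to 74715933. This assignment left 5 site and library pairs off pattern in total, against 7 for the next best.

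Fisher's exact test (2-sided) of detection against mutation, adjusted over 12 sites and 5 patterns, called CBS3 (p = 0.000333, adjusted 0.01998) and CBS4 (p = 0.000999, adjusted 0.02997). The 3 WT libraries had a peak at each of the 12 sites by definition, so these p-values overstate the evidence. The test was not run without WT. CBS5 (adjusted p = 0.1284), CBS1 (0.1284) and CBS2 (0.2323) did not pass in this exact test. CBS5 matched its pattern exactly, and its exact p of 0.01099 was the smallest that 2 libraries with it mutated allow. That is too large to pass over so many tests, so the result does not count against its loss. The 2 peaks over mutated CBS1 had their nearest summits 280 and 282 bp away. When a summit within 100 bp was required for detection, 3 HoxD sites were called. Among the other 47646 CTCF sites of the genome, 8 matched a pattern exactly (0.0168%, against 25.0% in the window; Fisher's exact p = 2.01e-09). The mutations were made in this cluster and its 12 sites were read from the same libraries, so this p measures no discovery. All 8 sites elsewhere matched the CBS1 pattern and had mean WT fold enrichments of 2.88 to 5.0, whereas CBS1 itself had 15.0. The 2 calls fell to 0, with 1 matching HoxD site, with only peaks of -log10 q of at least 10. They fell to 1 without either Del(CBS1-4) or either Del(CBS1-5) CTCF library. In these omissions the smallest possible p was larger, and 3 HoxD sites still matched exactly. Stratified by replicate number, neither CBS3 nor CBS4 passed (adjusted exact p = 0.1429 for both), although an exact match can give no smaller stratified p. The 8 matches elsewhere became 93, 62 and 22 without WT replicates 1, 2 and 3, 22 without Del(CBS1-3) replicate 1, and 47 and 15 without Del(CBS1-5) replicates 1 and 2.

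The other 7 CTCF sites of the window lay towards and beyond Evx2, a homeobox gene beside Hoxd13, and 5 of them were detected in all 14 libraries. The strongest of these, at 74673096 and 1493 bp from Hoxd13, stood at percentile 82.1 ± 13.3 (SD, n = 3) of the CTCF sites common to all lists in WT and at 82.7 ± 13.6 (n = 11) in mutants (exact permutation p = 0.9505). The pair at 74655517 and 74655823 lay in the Evx2 span, and the sites at 74661718, 74661969 and 74663755 in the span of Gm31790. The site at 74655823 was missing from 1 library, Del(CBS1-3) replicate 2. The site at 74635596, 17393 bp from Evx2, was found in 3 of 3 WT libraries and in 6 of the 10 with CBS1 mutated. Among the CBS themselves, CBS1 and CBS2 were the strongest in WT, at percentiles 85.5 ± 7.75 and 81.5 ± 23.0 (SD, n = 3). CBS5 stood at 56.7 ± 1.5, CBS3 at 25.9 ± 3.99 and CBS4 at 6.26 ± 6.9.

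**Figure D1:**
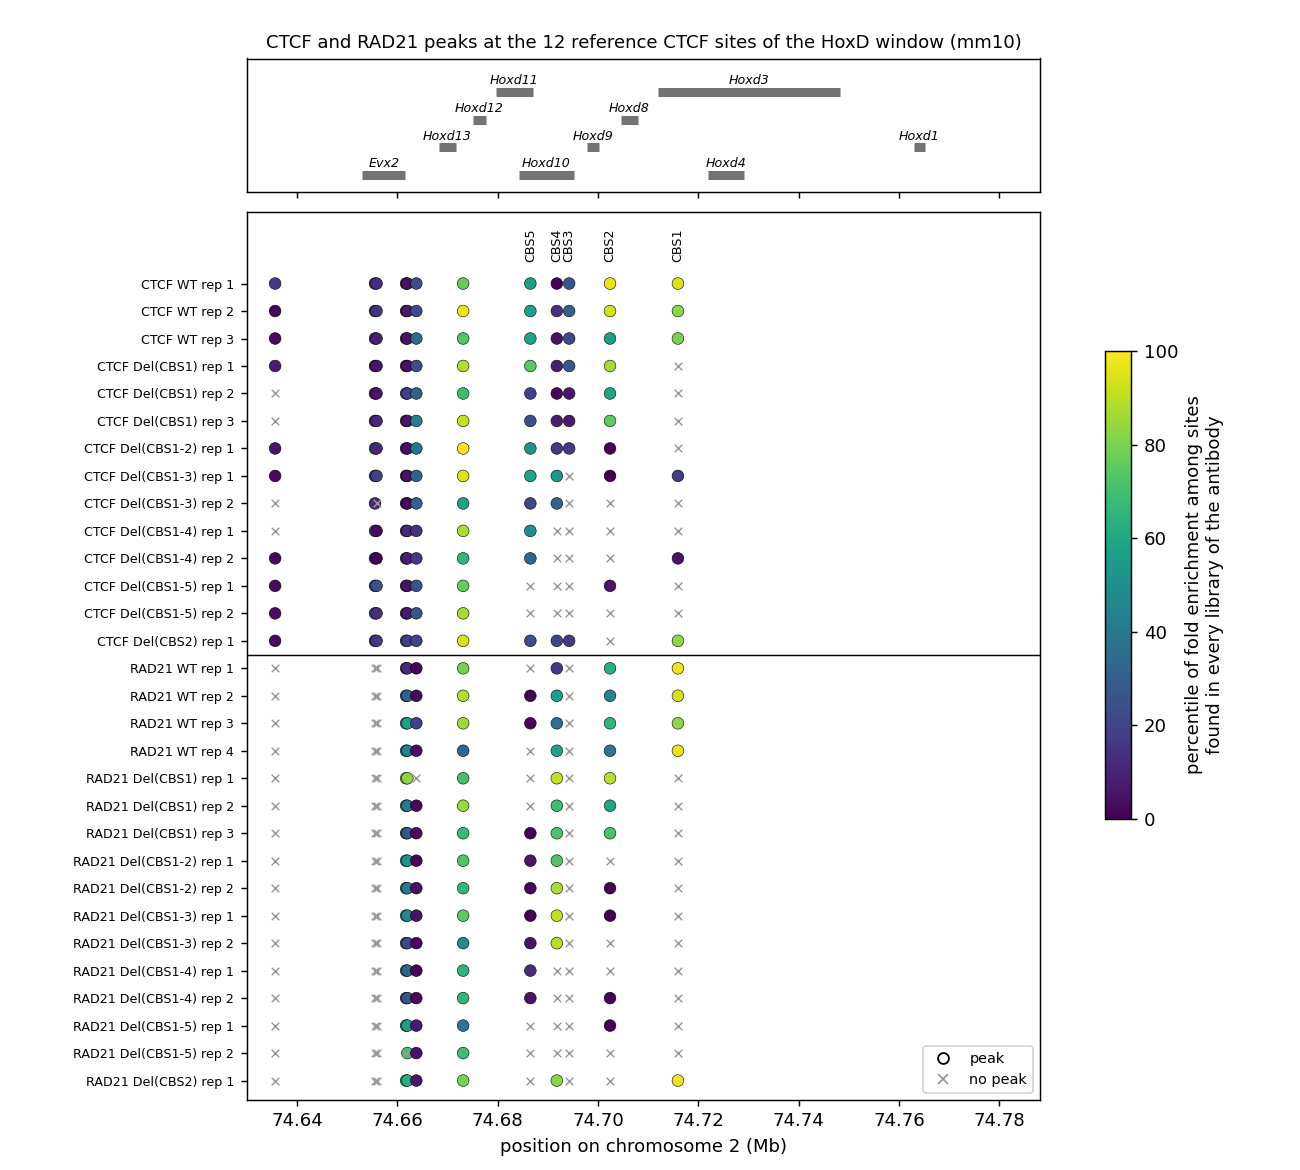
Map of the HoxD window on chromosome 2 (position in Mb, mm10), with the protein-coding genes above and each library as a line below; filled circles are peaks coloured by their percentile of fold enrichment among sites found in every library of the antibody, and crosses mark sites without a peak. CTCF at CBS3 was found in 0 of 6 libraries with it mutated, and RAD21 at CBS1 in 0 of 11.

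RAD21 was examined at the same positions to see where cohesin was detected once CTCF sites were mutated. At CBS1, RAD21 was found in 5 of 5 libraries with the site intact and in 0 of 11 with it mutated, and at CBS4 in 12 of 12 and 0 of 4. At CBS2 it was found in 7 of 7 and 4 of 9 libraries, and at CBS5 in 9 of 14, including 2 of 4 WT, and 0 of 2. The 4 RAD21 peaks over mutated CBS2 were weak, at fold 2.48 to 3.85 and percentiles 0.1 to 1.1. With CBS2 intact the folds were 8.82 to 12.6 and the percentiles 39.3 to 89.3. CBS3 had no RAD21 peak in any of the 16 libraries, WT included. Among 1935 CTCF sites of similar WT strength, 350 (18.1%) also had none, and the median was 10 libraries. Fisher's exact test called RAD21 loss at CBS1 (p = 0.0002289, adjusted 0.01374) and CBS4 (p = 0.0005495, adjusted 0.01648), and CBS2 had an adjusted exact p of 0.5048. The 2 calls fell to 1 without either Del(CBS1-4) or either Del(CBS1-5) RAD21 library, where the smallest possible p is larger. They also fell to 1 when any peak base within 250 bp counted as detection. Stratified by replicate number, neither CBS1 nor CBS4 passed for RAD21 (adjusted exact p = 0.119 for both), although an exact match can give no smaller stratified p.

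At the sites left intact, RAD21 enrichment was highest above WT at CBS4. RAD21 at CBS4 stood at percentile 41.4 ± 19.2 (SD, n = 4) in WT and at 81.7 ± 9.41 (n = 8) in the libraries that kept CBS4 but had other sites mutated, with 8 of 8 above the highest WT library (56.9). The mean was 77.2 in Del(CBS1), 79.9 in Del(CBS1-2) and 89.9 in Del(CBS1-3), and the Del(CBS2) library had 82.2. The difference of 40.3 had an exact 2-sided permutation p of 0.00202, the smallest that 495 permutations can give, and 0.0404 after adjustment over 20 such tests across the window; these tests were chosen after the data were seen. Leaving out any 1 of the 12 libraries ended this call (adjusted p = 0.05758 to 0.1212), although each exact p was then the smallest the fewer libraries allow and every remaining mutant library lay above every WT library. CTCF at CBS4 stood at 6.26 ± 6.9 (SD, n = 3) in WT and 20.2 ± 17.6 (n = 7) in mutants, which did not pass (exact p = 0.225). By allele, CTCF there was 6.1 ± 3.69 (SD, n = 3) in Del(CBS1), 17.3 in Del(CBS1-2), 42.4 in Del(CBS1-3) (n = 2) and 21.1 in Del(CBS2). At CBS2 in Del(CBS1), RAD21 stood at 73.1 ± 15.4 (n = 3) against 53.1 ± 13.3 (n = 4) in WT (exact p = 0.1714). Near Hoxd13, at 74673096, it stood at 66.8 ± 12.8 (n = 12) against 71.4 ± 26.5 (n = 4; exact p = 0.661). No RAD21 position in the window had a peak in both Del(CBS1-5) libraries and none in WT, a count of 0 that also held for the HoxA, HoxB and HoxC windows and has no test.

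**Figure D2:**
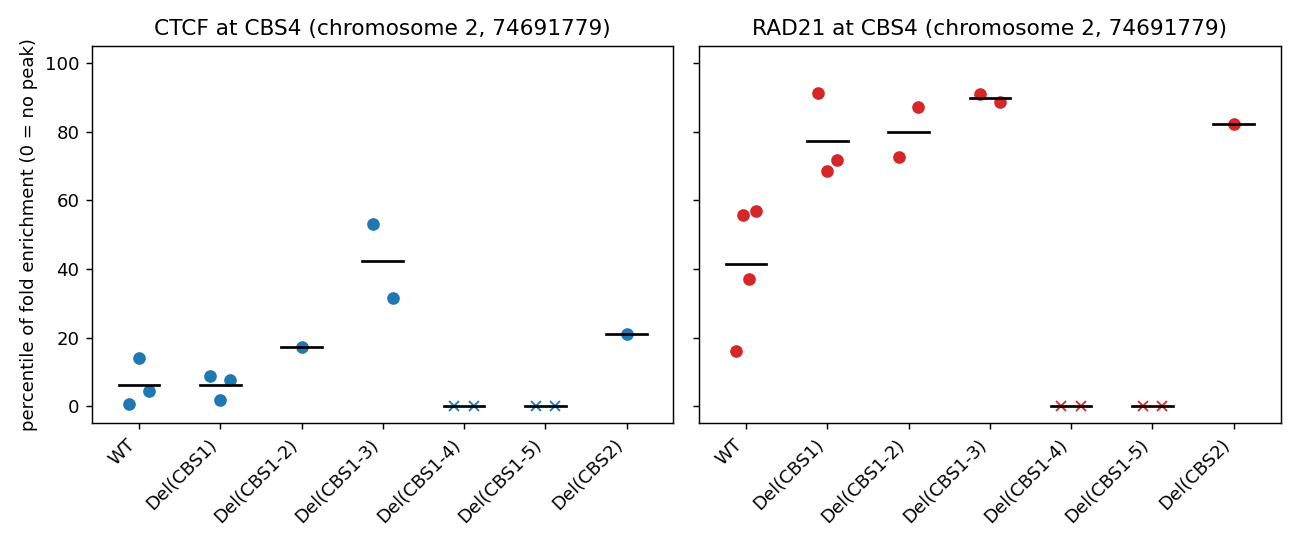
Percentile of fold enrichment at CBS4 (vertical axis, 0 to 100, 0 where no peak was found) by genotype, for CTCF and RAD21; each point is a library, crosses are libraries without a peak and bars are means. The 8 RAD21 libraries with CBS4 intact and another site mutated lie between 68.4 and 91.4, and the 4 WT libraries between 16.0 and 56.9.

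Loss and gain of CTCF sites across the genome were counted in the allele with the most mutated sites and in the allele with the most libraries. In Del(CBS1-5), 211 of 47658 CTCF sites (0.443%) found in all 3 WT libraries were in neither of the 2 mutant libraries, and 4 of them lay in the HoxD window. Of the 20 lost sites with a mean WT fold enrichment of at least 8, 3 lay in HoxD. The 5 strongest were CBS1 (fold 15.0), a site 5977 bp from Gm35657 on chromosome 9 (41190865; 13.3), CBS5 (11.5), and sites in Lrriq1 on chromosome 10 (103194774; 11.4) and Hmgcll1 on chromosome 9 (76123414; 11.3). The lowest WT -log10 q was 104 at CBS1 and 63.7 at CBS5, against 4.47, 5.36 and 7.42 at the sites near Gm35657, Lrriq1 and Hmgcll1. In the other direction, 781 of 55277 sites were in both mutant libraries and no WT library, 0 of them in HoxD. In Del(CBS1), 1405 of 47658 sites were lost, 1 of them in HoxD, and 15 of 36187 were gained. Del(CBS1) replicates 2 and 3 had shorter CTCF lists (40667 and 44550 peaks) than any WT library (52925 to 75027). List length was not separated from the allele in these counts.

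These counts of detected CTCF sites had no test in Del(CBS1-5). Leaving out a list raised them by the rule itself, since fewer lists then had to meet the condition. The rises below therefore do not show that the counts rest on single lists. The 211 lost sites became 987, 702 and 409 without WT replicates 1, 2 and 3 and 1653 and 423 without Del(CBS1-5) replicates 1 and 2, and the 781 gained became 3938 without WT replicate 3 and 2561 and 8118 without Del(CBS1-5) replicates 1 and 2. For Del(CBS1), the 1405 lost sites became 5066 and 2926 without WT replicates 1 and 2 and 7213 without Del(CBS1) replicate 1, and the 15 gained became 35, 34 and 69 without WT replicates 1, 2 and 3 and 92, 83 and 47 without Del(CBS1) replicates 1, 2 and 3.

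For RAD21, 859 of 20061 sites (4.28%) found in all 4 WT libraries were in neither Del(CBS1-5) library, and 2 of them lay in HoxD. The strongest was the CBS1 position in Hoxd3os1 (74715962; mean WT fold 14.6, lowest -log10 q 80.0). It was followed by sites 534 bp from Knl1, a kinetochore scaffold (chromosome 2, 119046585; 12.8), in Ptpa, an activator of a protein phosphatase (chromosome 2, 30435729; 12.2), in Txk, a T cell kinase (chromosome 5, 72710755; 11.5), and 252 bp from Prmt5, an arginine methyltransferase (chromosome 14, 54517722; 11.4). At those other sites the lowest WT -log10 q was 1.58, 7.36, 4.07 and 5.19. In the other direction, 12 of 15640 sites were gained, 0 of them in HoxD. In Del(CBS1), 78 of 20061 RAD21 sites were lost, 1 of them in HoxD, and 4 of 16995 were gained.

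The RAD21 counts also rose without the libraries named here, where again fewer lists had to meet the condition. The 859 became 2924 and 1403 without WT replicates 1 and 4 and 5366 without Del(CBS1-5) replicate 1, and the 12 gained became 25 and 27 without WT replicates 2 and 4 and 397 and 1158 without Del(CBS1-5) replicates 1 and 2. For Del(CBS1), the 78 lost became 568, 127 and 168 without WT replicates 1, 3 and 4 and 344 and 172 without Del(CBS1) replicates 2 and 3, and the 4 gained became 29, 10 and 12 without WT replicates 2, 3 and 4 and 1096, 21 and 30 without Del(CBS1) replicates 1, 2 and 3.

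Changes in relative enrichment were tested with limma on normal scores of each site's rank, over the sites found in every library of an antibody. CBS1 to CBS5 each lacked a peak in some libraries of either antibody, so none of them could be tested. In the HoxD window only the RAD21 sites at 74661981 and 74673086 and the 5 CTCF sites found in every CTCF library were tested. RAD21 in Del(CBS1-5) (n = 2) against WT (n = 4) was the only contrast with calls, at 6 of 12932 sites, none of them in HoxD (1236 sites at an unadjusted p under 0.05, 647 expected by chance). The site in Rwdd3 rose by 1.81 ± 0.33 (SE; chromosome 3, 121171748; adjusted p = 0.0204). The sites in Yeats4, a subunit of histone acetyltransferase complexes (-2.02 ± 0.36; chromosome 10, 117216969), and Wasl, the actin regulator N-WASP (-1.86 ± 0.34; chromosome 6, 24627860), fell, both with adjusted p = 0.0204. Sites in Mark3, a microtubule-affinity kinase (-1.78 ± 0.36; chromosome 12, 111653631), in Gm16193 and Mtus1 (-1.87 ± 0.38; chromosome 8, 41057295) and 15016 bp from Gm36237 (-1.75 ± 0.35; chromosome 3, 94902949) fell with adjusted p = 0.0478. The 6 calls fell to 0 without WT replicate 1, 2 or 3 or Del(CBS1-5) replicate 2, and to 1 with the weakest sites left out. They rose to 157 without Del(CBS1-5) replicate 1 and to 14 by rank of -log10 p.

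For CTCF (30976 sites), limma called 0 sites in the trend with the number of mutated sites (799 at an unadjusted p under 0.05, 1549 expected by chance), 0 in Del(CBS1-5) (498) and 0 in Del(CBS1) (1681). For RAD21 it called 0 in the trend (672 at an unadjusted p under 0.05, 647 expected) and 0 in Del(CBS1) (665). The CTCF site near Hoxd13 changed by -0.17 ± 0.44 (SE) in Del(CBS1-5) and the site in Evx2 at 74655517 by 0.47 ± 0.33, both with a limma adjusted p of 1. RAD21 near Hoxd13 had a value of -0.55 ± 0.38 (limma adjusted p = 0.664) and RAD21 in Gm31790 0.75 ± 0.40 (0.544). The CTCF count for Del(CBS1) became 3 and 1 without WT replicates 1 and 2, 13 without Del(CBS1) replicate 1 and 1 by rank of -log10 p; the count for Del(CBS1-5) became 1 without WT replicate 1 or 2. RAD21 in Del(CBS1) had 1 call without WT replicate 1.

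Among 12 gene lists fixed for the tissue and the locus, the other Hox clusters (HoxA, HoxB, HoxC and Evx1) were the only list called by camera, for CTCF. In the trend, 14 of 14 sites had a negative slope (median -0.062 per mutated site; camera adjusted p = 0.0103), and in Del(CBS1-5) 12 of 14 sites were lower (median -0.279; adjusted p = 0.0488). Neither call held with an estimated correlation (adjusted p = 0.528 and 0.888, respectively) or with fry (0.617 and 0.925), and the Del(CBS1-5) call was lost with sites within 50 kb of a gene. No single site passed over all sites or adjusted over the list alone. In Del(CBS1-5), the site at Hoxc8 had -0.67 ± 0.33 (SE, limma adjusted p = 1) and the site at Hoxa9 -0.58 ± 0.51 (1). RAD21 at the same clusters had 4 of 8 sites higher and 4 lower in Del(CBS1-5), and the site at Hoxa13 had -1.01 ± 0.36 (limma adjusted p = 0.339).

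The remaining lists had no call for either antibody or contrast. In the CTCF trend, sites with positive slopes numbered 2 of 5 in the HoxD cluster, 12 of 23 in imprinted domains, 6 of 13 in protocadherin clusters, 4 of 12 at neural tube genes and 1 of 9 at somite and muscle genes. They numbered 2 of 15 at limb and lateral plate genes, 3 of 8 at endoderm and liver genes, 4 of 7 at heart genes and 5 of 8 at blood genes. On the centromeric side of HoxD, between Atp5g3 and Evx2, 5 of 8 slopes were positive, and on the telomeric side, between Hoxd1 and Hnrnpa3, 8 of 12. The camera adjusted p was 0.0807 for the neural tube and for the limb lists. In CTCF Del(CBS1-5), 1 site on the centromeric side passed adjusted over the list alone, in 4930441J16Rik (-0.88 ± 0.28, SE), and 0 passed over all sites with limma. In RAD21 Del(CBS1-5), 13 of 16 sites in imprinted domains were higher (median 0.349, camera adjusted p = 0.336). Median, mean and test direction differed in sign in at least 1 contrast for the HoxD cluster and both its sides, the other Hox clusters (RAD21), imprinted domains, protocadherin clusters, and endoderm and liver genes.

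The share of RAD21 peaks lying over a reference CTCF site was compared across alleles. This share used the WT reference sites for every genotype, so it does not show whether cohesin and CTCF stayed together in mutants. It was 84.6% ± 7.75 (SD, n = 4) in WT and 83.0% ± 9.19 (n = 12) in mutants, a difference of -1.56 points that was smaller than the spread between libraries (exact 2-sided permutation p = 0.7478). Shares ran from 65.4% in Del(CBS2), which had 45618 separate RAD21 intervals, to 96.5% in a Del(CBS1) library. The shortest RAD21 list, Del(CBS1-5) replicate 2 with 16551 intervals, had 95.6%. With the same number of top peaks in every list the difference was -0.117 points (exact permutation p = 0.8236), and against each genotype's own CTCF peaks -2.94 (0.4253). With peaks of -log10 q of at least 10 it was 0.0618, without the single Del(CBS2) library 0.0427 and without WT replicate 1 2.03, each in the other direction.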

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

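No test in this part was chosen after its result was seen. Dixon's gap ratio was taken in 10 groups of the 4 WT RAD21 libraries: list length, the share of peaks over CTCF sites and the percentiles at 8 HoxD positions, of which 7 had distinct values. In 3 of these groups, all of them percentiles, 1 library lay far from the other three, which chance gives in about 1 of 20 groups. At 74663755, in the span of Gm31790, WT replicate 3 stood highest, at percentile 19.7. At 74673096, near Hoxd13, WT replicate 4 stood lowest, at 31.9. At 74686497, assigned to CBS5, WT replicate 3 stood highest, at 1.7, where 2 of the 4 WT libraries had no RAD21 peak. No biological explanation was tested for these values.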

How the results depend on the processing

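The CBS4 comparison, its alternatives, the omission of mutant libraries from the RAD21 share and the joint setting of a summit within 100 bp and -log10 q of at least 10 were chosen after seeing the data. Without leaving out a library, 114 alternatives were run: 69 kept the direction and side of the threshold or the count within 1.5 times, 44 moved and 1 reversed; the cause was not tested unless stated. The absence of gained RAD21 peaks in HoxD (0 in every alternative) and the RAD21 difference at CBS4 (40.6 by -log10 p, adjusted p = 0.0404) were among those that held. Only 12 of 15640 RAD21 sites were gained in Del(CBS1-5) over the genome, so a count of 0 in this window says little.

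With -log10 q of at least 10, fewer peaks remained: HoxD matches fell to 1 for CTCF (0 Fisher calls) and 1 for RAD21, and matches elsewhere to 1. CTCF sites lost and gained became 34 and 316 in Del(CBS1-5) and 634 and 0 in Del(CBS1); RAD21 sites 470 and 0, and 26 and 0. The RAD21 share difference reversed to 0.0618 from -1.56. The joint setting gave 1 CTCF match, 1 call, 2 matches elsewhere and 1 RAD21 match. A summit within 100 bp gave 14 matches elsewhere, 80 CTCF sites gained in Del(CBS1), 42 RAD21 sites gained in Del(CBS1-5), and 129 lost and 24 gained in Del(CBS1). Any base within 250 bp gave 1 RAD21 match and 1 call, 4 CTCF sites gained in Del(CBS1), and 7 and 8 RAD21 sites gained in Del(CBS1-5) and Del(CBS1). Allowing 1 library off pattern gave 88 matches elsewhere. Sites in at least 2 WT libraries, a larger set, gave 1671 and 6803 lost CTCF sites in Del(CBS1-5) and Del(CBS1), and 8681 and 3107 lost RAD21 sites.

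The labels give only a replicate number in common, and whether same-numbered libraries were prepared together is unknown. Deviations of same-numbered WT and Del(CBS1) libraries from their group means correlated at 0.27, 0.13 and 0.03 for CTCF and 0.28, 0.09 and 0.06 for RAD21, and WT replicates 1 and 3 but not 2 of each antibody correlated best with their own number. RAD21 shares over CTCF sites went with the number in WT (95.4%, 77.6% and 84.6% in replicates 1 to 3) and Del(CBS1) (96.5%, 77.3% and 84.3%). They did not in Del(CBS1-3) (81.5% and 93.0% in replicates 1 and 2) or Del(CBS1-5) (89.0% and 95.6%), so a pairing was not excluded. With replicate number as a block, the exact tests had 0 CTCF and 0 RAD21 calls, limma 1 call in the CTCF trend and 0 for RAD21 in Del(CBS1-5), and camera 2 lists in the CTCF trend; the block changed no other call, and the RAD21 share had a permutation p of 0.7976. By rank of -log10 p, CTCF Del(CBS1) had 1 call and RAD21 Del(CBS1-5) 14; the latter had 1 with the weakest 25% left out and 8 with centred log2 fold values. The CTCF list calls went to 0 in the trend and 0 in Del(CBS1-5) with an estimated correlation, to 0 and 0 with fry, and to 0 in Del(CBS1-5) within 50 kb.

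Leaving out 1 library at a time gave 3 to 3 CTCF matches in HoxD, 8 to 93 elsewhere and 1 to 2 Fisher calls, and 2 to 3 RAD21 matches with 1 to 2 calls. Lost and gained CTCF sites ran from 409 to 1653 and 959 to 8118 in Del(CBS1-5), and from 1544 to 7213 and 34 to 92 in Del(CBS1); every count exceeded the full one, since fewer lists had to meet the condition. RAD21 sites ran from 944 to 5366 and 12 to 1158, and from 99 to 568 and 5 to 1096. Rank calls ran from 0 to 0 in both trends, 0 to 1 and 0 to 13 for CTCF in Del(CBS1-5) and Del(CBS1), and 0 to 157 and 0 to 1 for RAD21. The RAD21 share difference ran from -3.89 to 2.03, reversing without WT replicate 1 and without Del(CBS2) (0.0427), and the CBS4 difference from 31.9 to 45.5, with an adjusted p of 0.05758 to 0.1212, so that each omission ended that call; with fewer libraries the smallest possible p is larger. Read depth was unknown, so no limit from depth could be given.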

Other observations

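The tests of RAD21 and CTCF at CBS4, the next intact site, pairs of lists matched in length, the peaks left over mutated CBS1 and CBS2 and the splits of lost sites were chosen only after the result was seen, and the readings of the CTCF linkage and next-site tests were made stricter, and CBS1 and CBS2 read apart, then.

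RAD21 at the next intact site towards Evx2 was compared allele by allele. In Del(CBS1) the next intact site, CBS2, stood at percentile 73.1 (n = 3) against 53.0 in WT (n = 4). Its exact permutation p was 0.1714, where 0.02857 was the smallest possible. In Del(CBS1-3) CBS4 stood at 89.9 (n = 2) against 41.4 in WT (n = 4), and in Del(CBS1-4) CBS5 stood at 8.75 (n = 2) against 0.45 (n = 4). Both of these had an exact permutation p of 0.06667, the smallest these group sizes allow, and 0.1667 after adjustment over the alleles. In Del(CBS1-2) CBS3 had no RAD21 peak in mutants or WT, and in Del(CBS1-5) the site near Hoxd13 stood at 54.0 (n = 2) against 71.4 (n = 4; exact p = 0.5333).

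RAD21 stood higher at CBS4 where other sites were mutated (81.7 against 41.4), a call that ended when any 1 library was left out. A shift of the WT lists against the mutant lists could not be tested with these values, because percentiles within a list remove a shift common to all its sites. Of 15163 RAD21 sites found in the same 12 libraries, only CBS4 (0.0066%) had every mutant library above every WT library by as much (36.6 points over these sites). By any amount, 23 (0.152%, against 0.202% by chance) were above. A rank difference as large was thus rare, but CBS4 was tested only after the data were seen. More CTCF at the same site cannot be told apart, since 4 of 7 CTCF libraries lay above the highest WT library; none of the 3 Del(CBS1) libraries did (6.1 against 6.27 on average), where RAD21 stood at 77.2, but CTCF and RAD21 came from different lists and so few libraries exclude no smaller rise. A gain of RAD21 at the next intact site was not seen in every allele: 3 of 5 had a higher mean, CBS3 had no peak in either group, and the site near Hoxd13 was lower by less than the spread of WT, so with 2 or 3 mutant libraries per allele these values do not decide it. As a hypothesis, cohesin may be held more often at CBS4 when neighbouring CTCF sites are mutated; litter, day of preparation and linked sequence variants were not tested.

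Many sites outside HoxD were absent from both Del(CBS1-5) lists. Weak sites missed by lists of these lengths may account for most of them: the pair of lists from other alleles nearest in length lacked 1016 RAD21 sites (859 in Del(CBS1-5)) and 264 CTCF sites (211), and the other CTCF pairs within 10% in length lacked 166 and 172. Different list lengths between WT and mutants were not settled by holding every list to the same number of peaks (172 of 13072 RAD21 and 332 of 44930 CTCF sites lost), and the bounds written beforehand were wrong, because this removes weak WT sites and shortens the mutant lists: with full mutant lists 15 and 85 of those sites were lost. For RAD21, 13 of 166 sites within 10 Mb of the window (7.83%) were lost against 810 of 19355 other autosomal sites (4.18%), with a one-sided Fisher's exact p of 0.0237 in 1 of 2 such tests and a 95% interval of the odds ratio of 1.01 to 3.45. A haplotype linked to HoxD may add some, but near and far sites were not matched for WT strength. The test therefore cannot tell linkage from weak sites missed. Linkage cannot be told apart for CTCF (3 of 376 against 198 of 45894, exact p = 0.225): the bound written beforehand, a rate ratio under 2, was met at 1.85, but it was too lax, because the interval of the odds ratio ran from 0.378 to 5.55.

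CTCF peaks remained over some mutated sites. At CBS1, all 10 libraries with it mutated had a weaker peak with its summit 213 to 424 bp away (fold 2.84 to 7.58, against 12.5 to 18.4 in WT), and 0 of the covering peaks had a summit within 100 bp, consistent with peaks beside the wild-type summit that reach over it in Del(CBS1-3) replicate 1 and Del(CBS1-4) replicate 2. At CBS2 that explanation is argued against, since 3 covering peaks had summits within 100 bp, at 16, 19 and 49 bp, the strongest in Del(CBS1-5) replicate 1 (fold 5.25, -log10 q 25.8). Binding left at the mutated CBS2 or reads from another embryo or library may be the source of these and were not tested.

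Other splits of the libraries were counted for Del(CBS1) against WT. For lost CTCF sites (1405) the highest other split of the 6 libraries gave 2049, and 3 of 10 splits gave as many; with 10 splits a share under 0.05 is out of reach. For lost RAD21 sites (78), 9 of 35 splits of the 7 libraries gave as many (highest other 893), so chance could not be excluded. The rank tests had 0 calls in the real split, so that every split gave as many by construction (10 of 10 for CTCF, highest other 7, and 35 of 35 for RAD21, highest other 5), which says nothing about chance. The split with 893 lost sites set WT replicates 2 and 4 with Del(CBS1) replicates 2 and 3; this is several times the real count. That split left the 2 shortest of the 7 lists, WT replicate 1 (22406 peaks) and Del(CBS1) replicate 1 (17996), among those without the sites, so list length went with it, and no test addressed this.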
